A study of Mus musculus with 2 samples.

How the data were processed

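The series holds 2 two-colour arrays of 3 monoclonal ZHBTc4 clones, stably transfected with EGFP, Oct4-EGFP or Nr5a2-EGFP. Per the labels, the cells grew without feeders in 15% serum with 1000 IU/ml LIF, were treated with doxycycline, and 10 µg of total RNA per channel was reverse transcribed from an oligo-dT primer with direct incorporation of the dye. Groups and dyes were taken from the labels: Cy3 held the EGFP clone on 1 array and the Oct4-EGFP clone on the other, and Cy5 held the Nr5a2-EGFP clone on both. The labels name no separate extracts of the Nr5a2-EGFP clone.

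The spot intensity values were deposited as scanner output of Agilent Feature Extraction, version 10.7.3.1 per the file headers, while the submitters' processing notes name version 9.3.2.1. Both arrays are of design 026655, with probe coordinates on mm9 per the file headers, and they share a slide and a scan. Whether extraction, labelling or hybridisation differed between them is not given in the sources used here. The processed intensity values were, per the file headers, background-subtracted with detrending and dye-normalized within the array. The log10 ratio of Cy5 over Cy3 in the files was computed by the same software, per the file headers, and its error, a score from the software's error model, was deposited beside it but not used here. Flags for saturation, for outlier spots and for spots well above background are also as the authors deposited them.

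The authors' deposited value table holds log2 ratios. Set against the scanner files, it followed the log10 ratio of Cy5 over Cy3 at r = 0.997 on both arrays, with medians of 0.03 (EGFP array) and 0.05 (Oct4 array). The correlation settles its direction but not its scale. On the EGFP array, 1797 genes had a log2 ratio of at least 1 and 2115 of at most -1 in the value table. The software's ratio, converted to log2, gave 1784 and 2127. How the value table was centred is not given in the sources used here.

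From the mean spot signal and the local background, normexp background correction with an offset of 50 and loess within each array were run in limma 3.58.1 (R 4.3.3), with control spots and outlier-flagged spots (530 on the EGFP array, 523 on the Oct4 array) given no weight in loess and left out afterwards. Saturated spots were kept. Saturated spots numbered 133 (Cy3) and 1213 (Cy5) on the EGFP array and 335 and 1245 on the Oct4 array. Single channels were scaled between arrays by Aquantile. Spots of a probe were averaged. Of 39429 probes, 399 were printed 10 times each, and the median SD of the log2 ratio among their spots was 0.068 (EGFP array) and 0.066 (Oct4 array), which covers technical error on the slide only. The number of arrays limits the precision of every other value.

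Gene names came from the files, updated by accession through a RefSeq gene table of mouse, where 26049 probes (66.1%) matched. For genes with several probes (6285 of 31896 names) the probe of highest mean intensity was used. Probes of a gene disagreed by a log2 ratio of at least 1 in 768 of 4923 such genes over EGFP, in 884 of 4907 over Oct4-EGFP and in 1094 of 5009 in the indirect comparison. A gene entered a comparison if it was well above background in at least 1 of its channels. Where 1 channel was saturated or not well above background, the ratio is only a bound and is given as at least N-fold, from levels after loess and Aquantile. The dim level was the higher of its own value and the lowest level of a probe well above background. Direct ratios and their bounds are open to dye bias, since no dyes were swapped, while bounds in the indirect comparison set Cy3 against Cy3.

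Before the data were examined, 31 gene lists were fixed, 1 of them the transgene genes alone, and so were the comparisons, the size rule and the rule for named genes. The rule took all probes of Nr5a2 and Pou5f1; in each comparison the 10 highest and 10 lowest genes with an official symbol and well above background in all channels and spots; the 6 members of the pluripotency and trophoblast lists and the 2 of every other list with the largest ratios; and Gapdh, Actb, Hprt and Tbp. Genes that the rule named in 1 comparison may be given in all, and some genes that it named are not reported here. A list's median was ranked among 10000 random lists matched on intensity in 20 bins, as a description of these arrays. With 1 array per pair of clones, no test was run between clones.

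The steps were tested on simulated arrays in which 200 of 31874 probes (EGFP array) or 31954 (Oct4 array) were given known folds, 50 probes per fold. Of those at 1.5-fold, 2% were called at least 2-fold on either array, of those at 2-fold 26%, of those at 3-fold 90% and 88%, and of those at 4-fold 96% and 100%. Unchanged probes were called 7 and 4 times. The simulated noise was normal, with an SD of 0.19 per channel and no dye effect specific to a gene. On the arrays, the Cy5 readings of the Nr5a2-EGFP clone were at least 2-fold apart in 1.72% of genes. The simulated calls of unchanged probes thus do not give the number of false calls on the arrays. The offset draws ratios toward 0, so that a simulated 2-fold had a median log2 of 0.80 (EGFP array) and 0.79 (Oct4 array). Lists shifted by 0.5 fell outside the 95% range in 58 of 60 simulations at 20 genes and in 60 of 60 at 45 genes, and unshifted lists in 3 and 2 of 60, over 26001 genes of the EGFP array.

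The alternatives were the software's own log ratio, the deposited value table, another offset, no background subtraction, median centring, single channels, other filters on dim, saturated and outlier spots, the mean over probes, the Nr5a2-EGFP channel of the other array, other fold thresholds and counts of probes. Summaries were computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.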

Results

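Gene expression was profiled in mouse ZHBTc4 embryonic stem (ES) cells, a line whose endogenous Oct4 alleles are disrupted and whose Oct4 comes from a transgene that doxycycline switches off. 3 monoclonal stable clones were hybridised on 2 two-colour oligonucleotide arrays after doxycycline treatment: EGFP clone 2-5, Oct4-EGFP clone 9 and Nr5a2-EGFP clone 26. On the EGFP array, Cy3 held the EGFP clone and Cy5 the Nr5a2-EGFP clone. On the Oct4 array, Cy3 held the Oct4-EGFP clone and Cy5 the Nr5a2-EGFP clone again. The arrays were read at 43020 spots each, and 79.3% (EGFP, Cy3), 78.9% (EGFP, Cy5), 80.1% (Oct4, Cy3) and 78.1% (Oct4, Cy5) of the spots lay well above background.

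Each pair of clones was measured on 1 array with no biological replicate and no dye swap, so no value below carries an error between cultures, and no test or p-value was possible. Each transgene was carried by 1 monoclonal clone, so its effect cannot be told apart from other differences between the clones. Genes were described by a fixed rule of size, a log2 ratio of at least 1 in either direction, written here as at least 2-fold higher or lower. The only repeated measurement was the Nr5a2-EGFP clone, read in Cy5 on both arrays. Its levels correlated at r = 0.994 across 23779 genes, and the SD of the log2 difference between its readings was 0.30 over 25509 genes. Of these genes, 438 (1.72%) were at least 2-fold apart between the readings.

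Nr5a2 read lower in the clone with its transgene, and Pou5f1 did not read at least 2-fold higher in the Oct4-EGFP clone than in the EGFP clone. Nr5a2 (NM_030676), a nuclear receptor of the Ftz-F1 family, had 2 probes on mm9 chromosome 1. The brighter, at 138740903 to 138740962, read lower in the Nr5a2-EGFP clone, with log2 ratios of -0.92 over EGFP and -1.14 over Oct4-EGFP. The dimmer, at 138741712 to 138741771, gave -0.39 and -0.63. Pou5f1 (NM_013633), which encodes Oct4, had 1 probe at chromosome 17, 35647280 to 35647340. It was dim, with processed signals of 118 in the EGFP clone, 116 in the Oct4-EGFP clone, and 104 and 28.8 in the readings of the Nr5a2-EGFP clone, the last not well above background, so that it was at least 1.87-fold lower there than in the Oct4-EGFP clone, with no upper bound. Its indirect log2 ratio, Oct4-EGFP over EGFP, was 0.78, or -0.02 from the Cy3 levels, while the readings of the Nr5a2-EGFP clone differed by 0.80. The files give the position of each probe but not which part of the transcript the transgenes carry, so these probes do not check the labels.

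The first comparison set the Nr5a2-EGFP clone against the EGFP clone, both after the doxycycline treatment that switches off the regulated Oct4. Most markers of trophoblast, the lineage that ES cells enter when Oct4 is lost, read within 2-fold of each other in the clones. Cdx2 (NM_007673, chromosome 5, 148112547 to 148112606), the transcription factor that specifies trophectoderm, had a log2 ratio of -0.34, Lcp1 0.34 and Phlda2 -0.06. Of the 43 measured members of the trophoblast list, 4 were at least 2-fold higher in the Nr5a2-EGFP clone and 3 at least 2-fold lower, where 8.41% of all genes were at least 2-fold apart. The pluripotency list also had few members on either side, 2 higher and 3 lower of 44.

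The 4 higher trophoblast genes were Peg10 (1.27), Gata3 (1.00), Wnt7b (1.01) and the glucose transporter gene Slc2a3, which was saturated in the Nr5a2-EGFP clone (at least 2.03-fold). The 3 lower ones were Hand1 (-1.27), a factor of giant cell differentiation, Ada (-1.21) and Nup62cl (-1.52, other probe 0.24). The list median was -0.03, above the medians of 2390 of 10000 random lists of the same size and intensity. The pluripotency median of -0.16 was above 297 of 10000. Its lower members were Esrrb (-2.30), an orphan nuclear receptor of naive ES cells, Fgf4 (-2.20) and the F-box gene Fbxo15 (-1.03). Esrrb was -0.85, Fgf4 0.73 and Fbxo15 -0.70 when the Nr5a2-EGFP level was taken from the Oct4 array instead. Its higher members were the T-box gene Tbx3, saturated in the Nr5a2-EGFP clone (at least 2.80-fold), and Tcf3 (1.76, other probe 0.24). The Tcf3 probe lies on chromosome 10 at the gene now called Tcf3, which encodes E2A, not at Tcf7l1, which the ES cell literature also called Tcf3.

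Across 26001 genes, 869 were at least 2-fold higher in the Nr5a2-EGFP clone and 1317 at least 2-fold lower. The highest ratios belonged to Ppp1r21 (4.01, other probe -0.20), the lymphotoxin gene Ltb (3.59), Tex13b (3.53), Gna12 (3.44) and the calcium-binding protein gene Cabp7 (3.34). Enah (3.12), which encodes an actin regulator, had 0.92 at its other probe. Nt5dc2 (2.80), Kcng4 (2.71), the Wnt inhibitor gene Dkk1 (2.70) and Trip11 (2.57) completed the 10 highest, and the other probes of Trip11 ranged from -0.18 to 0.36. The lowest was H19, an imprinted non-coding RNA, at -4.13, although its dimmer probe gave 0.11. Plcg1 (-3.81, other probe -0.62), Zscan4c (-3.54, other probes -3.48 and -0.38), Pla2g5 (-3.44, other probe -1.34), Fbln2 (-3.43), Meg3 (-3.37, its Nr5a2-EGFP readings 2.57 apart), Pcsk6 (-3.34), Vmn2r83 (-3.23) and the Y-linked Uty (-3.20) were also among the lowest.

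Genes of the 2-cell-like state, a rare state of ES cells in culture, included 5 lower and 1 higher member among 11 measured. Zscan4c led them, and Zscan4f, not well above background in the Nr5a2-EGFP clone, was at least 4.02-fold lower. The list median of -0.17 lay inside the range that held 95% of random lists. Of 32 imprinted genes, 6 were lower and 1 higher (Peg10), with a median of 0.18, or -0.06 as the mean over probes. The mesenchymal and fibroblast list (median -0.36, 0 higher and 3 lower of 23, led by Col5a1 at -1.78) and the p53 target list (-0.33, 0 higher and 1 lower of 20) were the 2 of 30 lists with medians outside that 95% range, both below it. Unshifted lists fell outside in 3 of 60 simulations at 20 genes and 2 of 60 at 45 genes. A number as small as 2 of 30 can thus arise without any shift. The mesenchymal median was -0.09 with no filter on background. The lower p53 target was Pmaip1 (-1.27), which encodes the pro-apoptotic NOXA, at -0.80 with the other array's Nr5a2-EGFP level. Known targets of Nr5a2 in liver and steroidogenic tissue had a median of -0.05. Of 19, the cholesterol carrier gene Star was higher (1.16) and 2 were lower, Ccnd1 (-2.34) most of all.

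The balance of the calls on the EGFP array depended on the scaling. With each array's ratios centred on the median in place of the intensity-dependent loess fit, 1556 genes were higher and 895 lower, so that higher genes made up 63.5% of calls in place of 39.8%. The median of all genes then stood at 0.16, beside 0.01 for the pluripotency list and 0.16 for the trophoblast list. The p53 and mesenchymal medians were then -0.17 and -0.15.

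**Figure D1:**
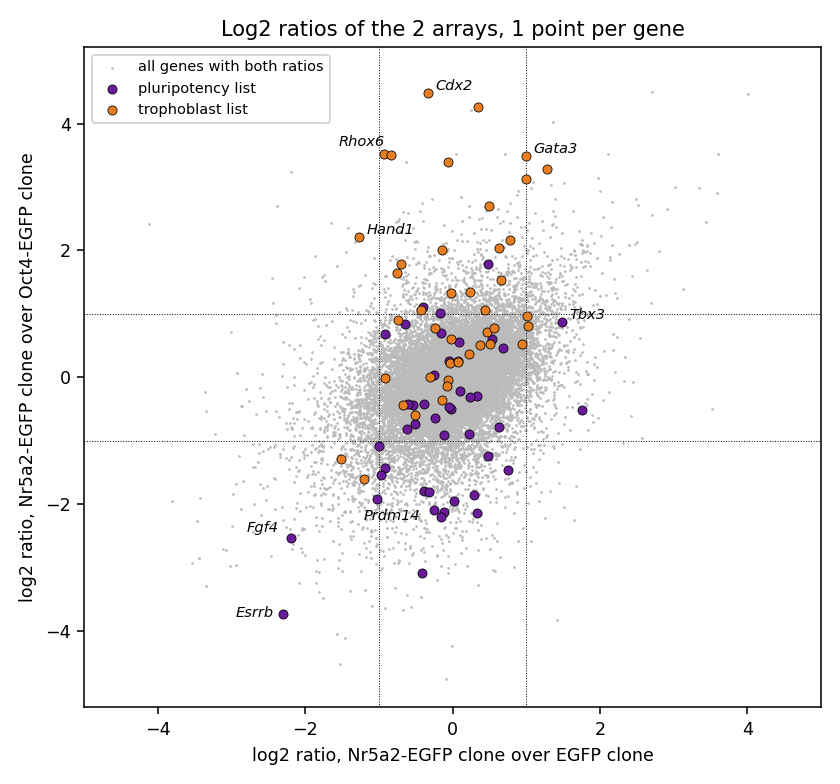
Each point is 1 gene, with the log2 ratio of the Nr5a2-EGFP clone over the EGFP clone on the horizontal axis and over the Oct4-EGFP clone on the vertical axis, where purple marks the pluripotency list, orange the trophoblast list, grey all genes with both ratios, and dotted lines log2 ratios of -1 and 1. Cdx2 lies at -0.34 and 4.48, and Esrrb at -2.30 and -3.72.

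The second comparison set the Nr5a2-EGFP clone against the Oct4-EGFP clone, both after the same treatment. Many trophoblast markers were higher in the Nr5a2-EGFP clone. Cdx2 read 22.4-fold higher (log2 ratio 4.48), Gata3, another trophectoderm factor, 11.2-fold (3.48), and the placental homeobox gene Rhox6 11.5-fold (3.52). Pluripotency genes were lower: Esrrb (NM_001159500, chromosome 12, 87862509 to 87862568) had a log2 ratio of -3.72, Nr0b1, which encodes the nuclear receptor Dax1, -3.25, and the forkhead gene Foxd3 -2.82. Of 46 measured trophoblast genes, 20 were at least 2-fold higher and 3 lower, and of 46 pluripotency genes, 3 were higher and 19 lower.

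The trophoblast list had a median of 0.79, above the medians of all 10000 random lists. Beyond Cdx2, Rhox6 and Gata3, its largest ratios were those of Lcp1 (4.25, other probe 0.97), Rhox9 (3.50), Phlda2 (3.39), an imprinted growth regulator of the placenta, and Peg10 (3.28), an imprinted gene needed for placenta formation. Hand1 had 2.21. The 3 lower members were Ada (-1.59), Nup62cl (-1.29, other probe 0.12) and the prolactin-family gene Prl8a9, whose ratio is only a bound because it was not well above background in the Nr5a2-EGFP clone, and which was named after its value was seen.

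The pluripotency median of -0.76 lay below the medians of all 10000 random lists. Prdm14 (-2.20), Zfp42 (-2.13), Fbxo15 (-1.92) and the threonine dehydrogenase gene Tdh (-1.45) were among the lower members, and Fgf4, saturated in the Oct4-EGFP clone, was at least 5.77-fold lower. The readings of the Nr5a2-EGFP clone were at least 2-fold apart for several of these genes, lower on the EGFP array for Esrrb (-1.45), Nr0b1 (-1.42), Prdm14 (-1.34) and Fgf4 (-2.93). Zfp42 was higher on the EGFP array (1.14), and its ratio was -0.99 with the Nr5a2-EGFP level of that array. The list median was -0.50 without genes at least 2-fold apart between the readings. The 3 higher members were Dnmt3l (1.79), Dppa2 (1.11) and Lin28a (1.02), the last 2 named after their values were seen. Also named after the values were seen, Klf4 had -2.12 and Sox2 -1.96, while Nanog had -0.41.

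**Figure D2:**
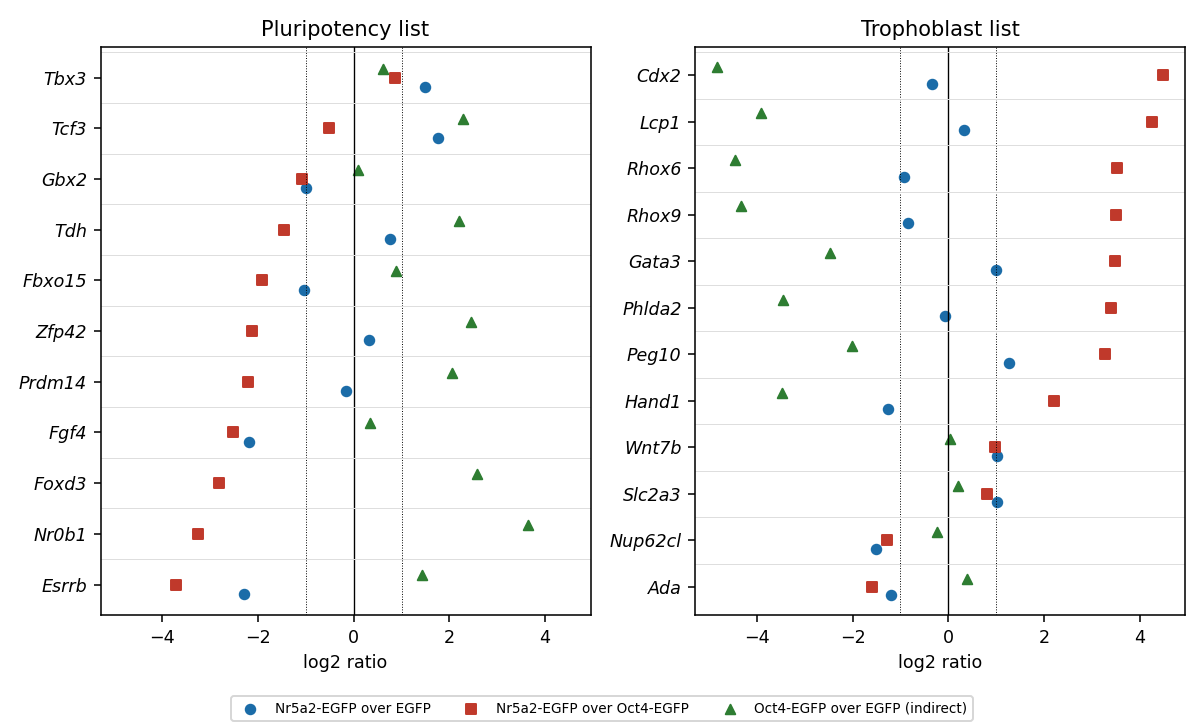
Log2 ratios of the pluripotency (left) and trophoblast (right) genes drawn from those the naming rule selected, with circles for Nr5a2-EGFP over EGFP, squares for Nr5a2-EGFP over Oct4-EGFP and triangles for the indirect Oct4-EGFP over EGFP, and dotted lines at -1 and 1; a ratio with a saturated channel or a channel not well above background is drawn at its measured value. Cdx2 runs from -4.83 to 4.48, and Nr0b1 and Foxd3 have no circle because neither was well above background on the EGFP array.

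Other gene groups differed too. Of 32 imprinted genes, 11 were higher in the Nr5a2-EGFP clone and 0 lower, with a median of 0.60 above all 10000 random lists. Of these, 4 are on the trophoblast list too, Phlda2 and Peg10 among them. Sfmbt2 (3.23) and H19 (2.42, dimmer probe -0.49, 0.97 as the mean over probes) were also higher. Of 23 epithelial genes, 6 were higher and 0 lower (median 0.61, above all 10000), with the polarity gene Crb3 at 2.04. Of these 6, 3 keratin genes are on the trophoblast list too, Krt18 (2.04) and Krt19 (1.64) among them. Of 21 p53 targets, 7 were lower and 0 higher (median -0.71, below all 10000), led by Pmaip1 (-2.79) and the desmosomal gene Perp (-2.24). Heat shock genes had a median of 0.61 (2 higher, Hsph1 at 1.54 and Bag3 at 1.01, and 0 lower of 10), above 9985 of 10000.

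Medians below the 95% range of random lists were also found for the mesenchymal and fibroblast list (-0.42, 2 higher and 4 lower of 23), the unfolded protein and integrated stress response (-0.41, 2 and 2 of 22), primitive streak and mesoderm (-0.40, 0 and 4 of 14), replication-dependent histones (-0.34, 0 and 3 of 45) and the Nr5a2 targets (-0.32, 0 and 2 of 20). Twist1 (-2.60), Chac1 (-1.99), Foxc2 (-1.83) and H2bu2 (-2.93) had the lowest ratios of the first 4, and Nr0b1 (-3.25), which is on the pluripotency list too, that of the last. In the mesenchymal list, Zeb2 went the other way (2.12, other probe 0.24). The cholesterol biosynthesis list lay above the range (0.28, 3 higher and 2 lower of 26). In all, 5 lists lay above the range and 7 below it.

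Across 26098 genes, 1185 were at least 2-fold higher in the Nr5a2-EGFP clone and 1856 at least 2-fold lower. Dkk1 (4.50, 22.6-fold) had the highest ratio. Cdx2, Ppp1r21 (4.47, other probe -0.12), Lcp1, the chitinase-like gene Chil1 (4.21), the pantetheinase gene Vnn1 (4.02), Rhox6, Cebpb (3.52), the alcohol dehydrogenase gene Adh1 (3.52) and Rhox9 made up the rest of the 10 highest. The 10 lowest were Cgnl1 (-4.75), which encodes a tight junction protein, Adcy10 (-4.52), Tmcc2 (-4.23), Tnmd (-4.10), Skida1 (-4.05), Aspdh (-3.82), Esrrb, Arl4d (-3.66, other probe -2.08), Tas2r125 (-3.64) and Dpp4 (-3.62). The readings of the Nr5a2-EGFP clone were at least 2-fold apart for Arl4d (-1.37) and Dpp4 (-1.55) too. The other probes of Adcy10 ranged from -0.25 to 1.18. Among reference genes, Gapdh had 0.01, Hprt 0.28, Tbp 0.44 and the beta-actin gene Actb 1.44, or 0.61 with the Nr5a2-EGFP level of the EGFP array.

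The third comparison, Oct4-EGFP over EGFP, was indirect: the difference of the log2 ratios of the arrays, in which a dye effect specific to a gene cancels. A difference between the readings of the Nr5a2-EGFP clone enters it too. The Oct4-EGFP clone read lower for trophoblast genes and higher for pluripotency genes than the EGFP clone. Cdx2 had a log2 ratio of -4.83 (28.3-fold lower), Rhox6 -4.46, Rhox9 -4.34, Lcp1 -3.92 (other probe -0.64), Hand1 -3.47 and Phlda2 -3.46. Zfp42 had 2.46, Tdh 2.20 and Prdm14 2.04, and the Cy3 levels alone gave 1.31 for Zfp42 and 3.38 for Prdm14. Of 45 trophoblast genes 1 was at least 2-fold higher in the Oct4-EGFP clone and 20 lower, and of 46 pluripotency genes 17 were higher and 5 lower.

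The trophoblast median was -0.63, below all 10000 random lists, and the pluripotency median 0.52, above all 10000. Nr0b1 and Foxd3 were not well above background in the EGFP clone, and the levels of the Cy3 channels put them at least 28.6-fold and 7.77-fold higher in the Oct4-EGFP clone. For Fgf4 the indirect log2 ratio was 0.33, but the Cy3 levels, saturated in the Oct4-EGFP clone, were at least 9.57-fold apart. Esrrb had 1.42, or 2.87 from the Cy3 levels. The 1 higher trophoblast gene was Prl8a9, whose ratio is only a bound because it was not well above background in the EGFP clone. The 5 lower pluripotency genes were Zscan10 (-1.60, or -0.90 as the mean over probes), Dppa2 (-1.51), Sall4 (-1.49), Dnmt3l (-1.30) and Lin28a (-1.18), of which only Dnmt3l is named by the rule and the others were named after their values were seen.

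Imprinted genes (median -0.56, 1 higher and 11 lower of 32) and epithelial genes (-0.58, 0 and 7 of 23) were lower in the Oct4-EGFP clone, with medians below all 10000 and below 9999 of 10000 random lists. Of the lower members, 3 imprinted and 2 epithelial genes are on the trophoblast list too. H19 had the lowest ratio of all genes the rule considered, -6.55 at its brighter probe and 0.60 at the other. Sfmbt2 had -5.43, and the epithelial gene Cldn3 -2.80. The primed epiblast list had a median of -0.49 (0 higher and 5 lower of 15), which was -0.07 when the mean over all probes of a gene was taken. Replication-dependent histones had a median of 0.31 (2 higher and 1 lower of 45), above 9990 of 10000 random lists. Reference genes (median -0.38, 0 higher and 1 lower of 15) lay below their range too, with Actb at -1.77, or -0.94 from the Cy3 levels.

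In total 1708 genes were at least 2-fold higher in the Oct4-EGFP clone and 1542 at least 2-fold lower among 26343. The Cy3 levels alone gave 2285 higher and 2052 lower. The 10 highest were Aspdh (5.24), Tmcc2 (4.22), Tex13b (4.02), Tmem63a (3.90), Stmn2 (3.63), Htr1d (3.58), Trip11 (3.53), Tbx20 (3.46), Ndufa4l2 (3.46, its Nr5a2-EGFP readings -1.37 apart) and Olfml2b (3.38). For Trip11 and Tbx20 other probes ranged from -0.64 to 0.30 and from -0.11 to 1.19. After H19, Sfmbt2, Cdx2, Rhox6 and Rhox9, the lowest were the homeobox gene Rhox10 (-4.08), Dmrtc1b (-4.03), Chil1 (-3.96), Lcp1 and the nitric oxide synthase gene Nos1 (-3.78).

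**Figure D3:**
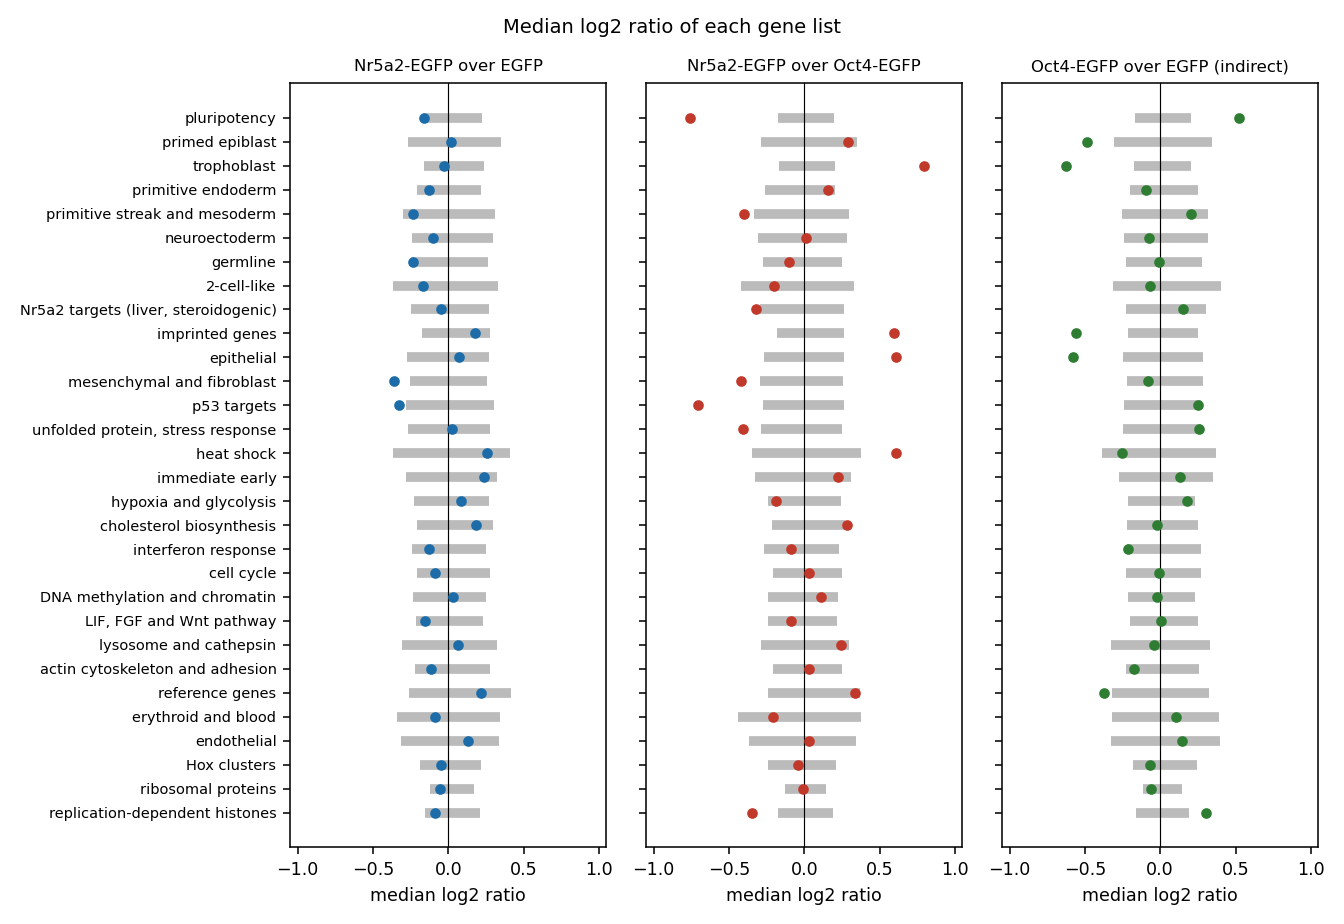
Median log2 ratio of each of 30 gene lists (points) in the 3 comparisons, with grey bars for the range that held 95% of 10000 random lists of the same size and matched intensity. The pluripotency list lies at -0.16, -0.76 and 0.52 and the trophoblast list at -0.03, 0.79 and -0.63, from left to right.

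The direct ratios of the arrays were also set against each other. Of genes with a ratio on both arrays, 287 were higher in the Nr5a2-EGFP clone in both comparisons, among them Dkk1, Ppp1r21, Ltb, Gna12 and Peg10, and 471 were lower in both, among them Esrrb, Pcsk6, Pla2g5, Zscan4c and Ccnd1. Another 33 genes were higher over EGFP and lower over Oct4-EGFP, and 44, among them H19, Sfmbt2 and Hand1, were lower over EGFP and higher over Oct4-EGFP. Independent lists of these sizes would share 40.1, 88.6, 58.8 and 60.5 genes in the same order.

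Across 25197 genes, which are not independent replicates, the ratios correlated at r = 0.42 (Spearman rho 0.41). Both ratios contain the Nr5a2-EGFP clone, and the observed covariance was 0.171. In 100 simulations of unchanged clones, 1 reading of the shared clone entered both ratios, which gave a mean r of 0.50 and a covariance of 0.0375. That setting fixes r near 0.50 in advance. On the arrays the clone was read separately, so the simulated values are no measure for the observed ones. With the Nr5a2-EGFP level of the other array in each ratio, r was 0.13. The arrays had 1 clone in common, in Cy5 on both without a dye swap, and no second culture of it. Neither the correlation nor the number of shared genes can thus be set apart from the sharing of that clone and its dye.

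**Figure D4:**
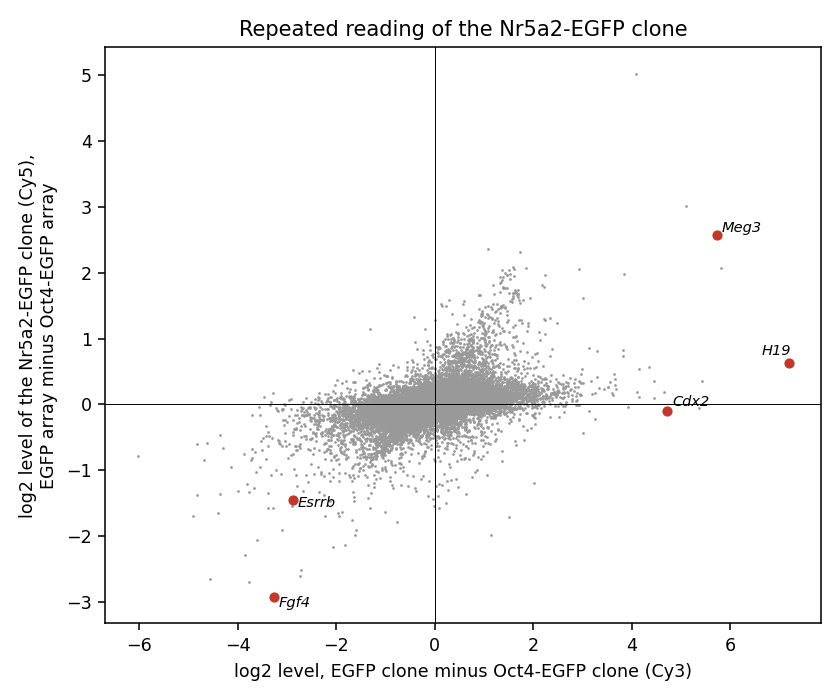
Each point is 1 gene, with the log2 level in the EGFP clone minus that in the Oct4-EGFP clone (both Cy3) on the horizontal axis and the difference between the readings of the Nr5a2-EGFP clone (Cy5, EGFP array minus Oct4 array) on the vertical axis. Only genes well above background in all 4 channels are drawn. Most of them lie near 0 on the vertical axis (SD 0.27 over 23779 genes), Cdx2 at -0.10, while Fgf4 lies at -2.93 and Meg3 at 2.57.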

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

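The alternative that leaves out genes at least 2-fold apart between the readings of the Nr5a2-EGFP clone was chosen after the data were seen, as were some of the named genes, and the other alternatives were planned. Under them 81 counts stayed within 1.5 times the reported count and 25 did not. For the pluripotency and trophoblast lists 72 medians moved by less than their bootstrap SD and 4 by more, and for other lists 1044 and 56. Of the ratios of named genes, 6520 moved by less than 0.30, the SD between the readings, 574 moved further, and 5 called ratios changed sign. Part of this agreement was fixed in advance. The filters on background (538 and 568 of the 6520) and leaving out genes with disagreeing readings (527) only add or drop genes. Keeping outlier-flagged spots (568) or leaving out saturated ones (545) does the same for probes printed once, 39030 of 39429. With no background subtraction (568), median local backgrounds of 42.5 to 47 stay in the signal, close to the offset of 50 that the main setting adds. Single channels leave the direct ratios, and so the direct counts, as they were. No paired analysis was possible because each pair of clones was measured once.

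The software's log ratio, without the offset, gave 1784 genes higher and 2127 lower over EGFP, 1958 higher over Oct4-EGFP, 2594 higher and 2467 lower in the indirect comparison, 780 apart between the readings, and r = 0.46 between the arrays. The value table gave 1797 and 2115 over EGFP, 2046 higher over Oct4-EGFP, 2507 lower in the indirect comparison and r = 0.45. Under the software's log ratio 97.9% of the reported calls over EGFP and 97.8% over Oct4-EGFP were kept. Correlations were 0.44 with offset 0 and 0.41 with no filter on background. Median centring gave 1556 genes higher over EGFP, medians of 0.0057 (pluripotency) and 0.16 (trophoblast) there, and r = 0.44, with 79.0% of the reported calls over EGFP kept. At 1.5-fold the counts were 3269 higher and 3701 lower over EGFP, 3316 and 4177 over Oct4-EGFP, 4175 and 3794 in the indirect comparison, and 1245 apart between the readings. At 3-fold they were 160 and 327, 359 and 657, 552 and 449, and 144, by the construction of the threshold.

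With the Nr5a2-EGFP level of the other array, the pluripotency median over EGFP was -0.058 and r was 0.13. The counts over EGFP rose to 1263 higher and 1685 lower, from 869 and 1317. Over Oct4-EGFP they rose to 1633 and 2240, from 1185 and 1856. Direct ratios within an array may thus be drawn toward 0, and some genes read as within 2-fold may differ by more. Of the called named genes, 81 of 93 over EGFP and 125 of 134 over Oct4-EGFP were still at least 2-fold with the other array's level. Under it 3 ratios over EGFP changed sign: Fgf4 to 0.73, the chromatin remodeller gene Smarca4 (-1.17) to 0.12, and the imprinted Igf2 (-1.42, chosen after its value was seen) to 0.15. Rps3a1 in the indirect comparison (1.26) was -0.24 from single channels, and Pax6 over Oct4-EGFP (1.26) was -0.0032 as the mean over probes, since its other probe gave -1.27. Without genes at least 2-fold apart between the readings, the pluripotency median over Oct4-EGFP was -0.50. Except for the changes by construction and by other probes, the cause was not tested. Signal over background limits the ratios of dim probes, which the offset draws toward 0.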

Other observations

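In this part, the test of GC content on chromosome 1 was set before its result was seen, and all other tests were chosen after. The remaining gene groups were summarised in the same way. Among germline genes, 0 were higher and 3 lower over EGFP (median -0.24 of 22), 4 and 2 over Oct4-EGFP (-0.10), and 0 and 6 in the indirect comparison (-0.01). Stra8, which germ cells need to enter meiosis, had a log2 ratio of 2.82 over Oct4-EGFP and -3.09 in the indirect comparison, and the meiotic gene Hormad1 -2.06 over EGFP and -2.69 over Oct4-EGFP. Primitive endoderm genes had medians of -0.13, 0.16 and -0.09 in the order EGFP, Oct4-EGFP and indirect, and the laminin gene Lamb1 -0.71, 1.63 and -2.34. In the same order, primed epiblast genes had 0.02 and 0.29 in the direct comparisons, neuroectoderm genes -0.10, 0.01 and -0.08, Hox genes -0.05, -0.04 and -0.07, erythroid genes -0.09, -0.21 and 0.10, and endothelial genes 0.13, 0.03 and 0.14. The neural factor gene Sox1 had -2.55 over Oct4-EGFP, but its other probe gave -0.50.

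Of 30 genes of the LIF, FGF and Wnt pathways, 4 were higher and 6 lower over Oct4-EGFP (median -0.09, with -0.15 over EGFP and 0.00 in the indirect comparison). The ERK phosphatase gene Dusp6 had -2.68 there and the Wnt target Sp5 1.88. Among 28 genes of DNA methylation and chromatin (0.03, 0.11 and -0.02), the de novo methyltransferase gene Dnmt3a had 1.25 over Oct4-EGFP and -1.76 in the indirect comparison. Immediate early genes had medians of 0.24, 0.23 and 0.13, with Myc at 1.66 over Oct4-EGFP, and hypoxia and glycolysis genes 0.08, -0.19 and 0.18, with the mitophagy gene Bnip3 at 2.11. Lysosome and cathepsin genes had 0.06, 0.24 and -0.04, with Ctsb at 1.65 over EGFP and 1.46 over Oct4-EGFP. Interferon response genes had -0.13, -0.09 and -0.21, with the immunoproteasome gene Psmb8 at -2.10 over EGFP. Cell cycle genes had medians of -0.09, 0.03 and -0.01, with at most 1 higher and 1 lower in each comparison. Actin and adhesion genes had -0.11 (1 higher and 4 lower of 29), 0.03 (3 and 3 of 30) and -0.18 (2 and 4 of 29). Ribosomal protein genes had -0.06, -0.01 and -0.06, but they read higher in the Nr5a2-EGFP clone on the EGFP array than on the Oct4 array (median 0.28, 9 higher and 1 lower of 80). The transgene genes had medians of -0.52, -1.02 and 0.50.

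Y-linked genes of these mouse cells, Uty apart chosen after their values were seen, did not all differ between clones. Ddx3y had log2 levels of 12.11 in the EGFP clone, 7.01 in the Oct4-EGFP clone, and 10.66 and 7.64 in the readings of the Nr5a2-EGFP clone on the EGFP and Oct4 arrays. Eif2s3y had log2 ratios of -2.68 over EGFP and -1.41 over Oct4-EGFP. Uty was at least 11.7-fold lower in the Oct4-EGFP clone than in the EGFP clone. Zfy2, well above background in all 4 channels, had -0.12 over EGFP, 0.09 over Oct4-EGFP and -0.21 in the indirect comparison, and Kdm5d, Usp9y, Zfy1 and the other probe of Uty were not well above background in any channel.

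The readings of the Nr5a2-EGFP clone differed between the arrays toward the clone hybridised beside it, with a correlation of 0.49 between Cy5 and Cy3 differences across 22622 genes, which are not independent, and a slope of 0.17. Of 321 genes at least 4-fold higher in the Oct4-EGFP clone, 287 shifted that way, and of 256 at least 4-fold higher in the EGFP clone, 226. Spot effects shared by both dyes would shift genes alike whatever their ratio, but the shift was larger where Cy5 was low beside Cy3, by at least 0.16 (SD 0.03). A fixed share of Cy3 signal read in Cy5 may remain in part. The median shift lay below what the fifth lowest ratio on an array allows on both arrays, with a difference of -0.044 on the EGFP array. It lay above what the lowest ratio, that of 1 gene, allows: 0.35 (SD 0.03) against 0.21 on the Oct4 array. On the EGFP array it was 0.19 (SD 0.01) against 0.15. Such a share could be the whole cause only if the lowest ratios were read too low. The labels name no extracts, so different extracts of the clone could also underlie the correlation of 0.49, and no biological explanation was tested.

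The probes of Nr5a2 read lower in the Nr5a2-EGFP clone, and that of Pou5f1 did not read at least 2-fold higher in the Oct4-EGFP clone than in the EGFP clone. Its Cy3 log2 levels were 7.59 and 7.61, and its indirect log2 ratio of 0.78 rests on Nr5a2-EGFP readings 0.80 apart. A swap of the EGFP and Oct4-EGFP samples would put trophoblast genes higher and pluripotency genes lower in the clone labelled Oct4-EGFP, if Oct4 holds these cells in the ES state. The trophoblast median there was -0.63 (bootstrap SD 0.36), within 2 SDs of 0 with 1 gene higher and 20 lower, and the pluripotency median, tested later, was 0.52 (SD 0.20), which argues against a swap. The probes may lie outside the part of the transcript that the transgenes carry. Those of Nr5a2 start at positions 2109 and 2918 of its transcript, and that of Pou5f1 at position 903 of its own. The files do not give the part that the transgenes carry, so this stays open for both genes.

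Genes of chromosome 1 beyond 70 Mb, a boundary set from the window medians and a segment that holds Nr5a2 itself, read higher in the Nr5a2-EGFP clone, with a median log2 ratio over 883 genes of 0.20 over EGFP and 0.16 over Oct4-EGFP, against 0.03 in the indirect comparison and -0.01 for 357 genes up to 70 Mb. After the trend with probe GC was removed the smaller median was still 0.16 (SD 0.02), which argues against GC content as the whole cause. Both direct comparisons share the Nr5a2-EGFP clone in Cy5 without a dye swap, so they do not repeat the pattern independently. A dye effect on these probes would enter both and cancel in the indirect comparison, and apart from probe GC it was not tested. Additional copies of the segment in some or all cells of the clone may remain as a hypothesis, and 3 copies in place of 2 would give 0.58. The run of 8 windows of 10 Mb above the genome's median in both direct comparisons was matched in 5 of 1000 shuffles, the longest 9, so the test set for it was not met. Leaving out windows under 20 genes, a step added afterwards that removed 1 window of 6 genes from chromosome 1, gave a run of 12 against at most 10, and a region of chromosome 14 up to 10 Mb (46 genes) read higher too, at 0.40 and 0.51.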
